A study of Drosophila melanogaster with 30 samples.

How the data were processed

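The series holds 30 libraries of reporter inserts recovered by PCR from sorted cells of Drosophila embryos, 18 in round 1 and 12 in round 2. Populations were assigned from the labels: low-GFP CD2+, CD2+ and CD2- cells in round 1, low-GFP CD2+ and CD2+ cells in round 2. The series title carries a tag of another assay, HiChIP, while every library is described as inserts recovered from sorted cells and was analysed as such. Experiment 1 covers replicates 1 to 3 and experiment 2 replicates 4 to 6 of each round. Replicates are collection days, each with its own cages of embryos, and the dates in the labels pair the populations of a day. The pairing was checked by correlating, within each experiment, the deviations of log2 CPM from the mean of each population between the libraries of a day: 17 of 18 pairs exceeded 0.1 in round 1 (median 0.223, smallest 0.0954) and 6 of 6 in round 2 (median 0.476, smallest 0.101).

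The authors deposited, for each library, tables of counts of reads mapped to each barcoded element, 1 for read 1 and 1 for read 2 of a pair. Per the submitters' processing notes, DESeq was used; its version, the mapper and the mapping reference are not given in the sources used here. Empty cells were read as 0. The authors also deposited 4 comparison tables, 1 per round and experiment, with a ratio (the fold change of low-GFP over control means), its log2 value, a p-value with its adjusted form, and normalized means. Per the file headers these other values are base means, and a linear fit showed that the deposited means equal averages of read 1 plus read 2 counts over 1 factor per library (relative error under 1e-09). In 1 of these tables a log2 fold change cell holds a spreadsheet error where the ratio is 0. The comparison tables were used for the counts at the end of the report and for 1 alternative scaling, and all other values were computed from the counts.

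Read 1 counts were used throughout. Read 1 and read 2 log2 counts correlated at 0.996 or more in every library. Depth ran from 3399506 to 5934098 read 1 counts in round 1 (low-GFP 4180158 to 5443087, CD2+ 3399506 to 4917450, CD2- 3497557 to 5934098) and from 2928510 to 5488936 in round 2 (low-GFP 2928510 to 4584710, CD2+ 3477673 to 5488936). The floor for a count of 0 was 3 counts of the library total. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only. Libraries of the same group correlated at 0.61 to 0.90, and their scatter exceeded counting error by a chi-square per degree of freedom of 3110 or more. The numbers of cells and template molecules behind the reads are not known, so their sampling is not separated from differences between days. The fitted biological coefficient of variation was 1.46 in round 1 and 1.10 in round 2.

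Fits used edgeR 4.0.16 in R 4.3.3, with filterByExpr at a minimum count of 10, TMM scaling, a quasi-likelihood fit with population and experiment as terms, and Benjamini-Hochberg adjustment over all elements tested in a comparison. An element was called at an adjusted p under 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It therefore restates the test and is not a separate estimate. CPM values are scaled by TMM and can exceed raw shares, and daily log2 CPM differences used a prior count of 2. The comparisons were low-GFP against both controls (round 1), low-GFP against CD2+ (both rounds), CD2+ against CD2-, each low-GFP comparison within each experiment (against both controls in round 1), and the interaction of experiment and population. Shares of counts were compared by exact two-sided sign-flip tests over 6 collection days, adjusted over 8 tests. Overlaps of calls used Fisher's exact test. The tests of rare elements in the closing section replaced earlier ones, on read counts and on signs in the libraries that had selected the elements, whose outcome the selection largely fixed, and the test of E. coli elements in round 1 was extended by the camera result of the class; both changes were made after the results were seen. The single-experiment test took 4 forms, all after the results were seen: signs of fold changes in the 12 elements tested in both experiments (excluded), calls over all 15 with untested ones counted as not called against a bar of 80% (undecided, the form reported), the same against a bar of 50% (excluded, withdrawn), and calls over the 12 against 80% (excluded, withdrawn because being tested depends on the low-GFP counts). Correlations were taken across elements.

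The comparisons with their tests, 8 lists of genes and the rule for naming elements were fixed before the data were examined, while some alternatives and some tests of the closing section, named where they appear, were chosen or changed afterwards. The lists hold 150 gene names, of which 139 matched a current symbol in a name table of genome release 6. A gene symbol could be read from the names of 292 elements. Lists with at least 3 tested elements were tested with camera and fry of limma 3.58.1, camera with a preset correlation of 0.01 and again with an estimated correlation. Name classes (elements named after a gene, CtBP or Groucho regions, E. coli controls and others) were formed after the files were seen. Elements were named if they were among the 15 highest or 10 lowest called with the same sign on every collection day of a pooled comparison, if called in the same direction in both rounds, or if among the 4 largest absolute fold changes of a list. Further elements are stated to be chosen after their values were seen, or belong to a count of 5 or fewer.

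Alternatives fixed in advance were DESeq2 1.42.0 with its size factors, total counts in place of TMM, read 2 counts, read 1 plus read 2 counts, no filter beyond 1 count, at least 100 counts in every library of 1 population, collection day as a replicate block, no experiment term, and leaving out each day or library in turn. Chosen after seeing the data were the size factors of the authors on read 1 plus read 2 counts, scaling to the summed E. coli control elements, and leaving out the low-GFP library of day 4 of round 1.

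The pipeline was tested on simulated data with the dispersions fitted by edgeR, 60 of 358 elements changed in round 1 and 21 of 155 in round 2. There were 10 sets per comparison for edgeR and 3 for DESeq2. With edgeR the pooled fits recovered 16.0%, 55.3% and 78.9% of elements changed 4-, 16- and 64-fold in round 1 against both controls, 8.00%, 49.2% and 69.8% against CD2+ cells, and 31.9%, 69.1% and 90.0% in round 2. Within experiments recovery at 16-fold was 30.7% and 23.0% in round 1 and 60.0% and 21.7% in round 2, and for the interactions 7.04% and 17.1%. False calls made up 0.415% to 6.56% of edgeR calls and 4.08% to 37.0% of DESeq2 calls. For the list test, 1 list of 10 independently drawn elements, all raised 4-fold, was found in 10 of 10 sets in both rounds. Of 200 unchanged lists, 5 and 7 were called. Both were judged by an unadjusted camera p under 0.05 with the preset correlation. Smaller lists, lists of mixed direction and adjusted p-values were not covered.

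Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Element sequences and genome positions were not used here, so elements are given by name alone.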

Results

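The data were counts of barcoded candidate regulatory elements recovered from sorted cells of Drosophila embryos. Each element sat in a reporter in which a strong ubiquitous enhancer drove GFP, and males carrying random picks of the pool were crossed to twi:CD2 females, so that an antibody to CD2 marked mesodermal cells. An element that silences the reporter in mesoderm places its carrier cells in the low-GFP part of the CD2+ population, and the libraries count how often each element was recovered from that part and from control sorts. Round 1 used 576 elements and 18 libraries, 6 each from low-GFP CD2+ cells, all CD2+ cells and CD2- cells. Round 2 used 188 elements and 12 libraries, 6 each from low-GFP CD2+ and all CD2+ cells. Every group had 1 library from each of 6 collection days, days 1 to 3 forming experiment 1 and days 4 to 6 experiment 2. Read 1 counts per library ran from 3399506 to 5934098 in round 1 and from 2928510 to 5488936 in round 2. A library held between 316 and 371 of the elements in round 1 and between 154 and 163 in round 2. In round 1, 207 elements were present in every library and 160 in none, against 137 and 16 in round 2. A count of 0 allowed an abundance of up to 0.506 to 0.882 CPM (counts scaled to library size) in round 1 and up to 0.547 to 1.02 CPM in round 2.

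Low-GFP cells of round 1 were compared with the CD2+ and CD2- sorts together, to find elements recovered more often from mesodermal cells with weak GFP. Of the 57 elements called higher, 15 were rare in both controls, with a mean under 20 CPM. The Z600_z600-lacZ element, of a gene whose product blocks mitosis in the gastrulating embryo, reached 1836 ± 901 CPM (mean ± SD, n = 6) in low-GFP cells against 2.83 ± 1.91 CPM in CD2+ and 2.13 ± 2.43 CPM in CD2- cells. Its log2 fold change was 9.99 (SE 1.03, edgeR adjusted p = 1.60e-06). CAD2_sns, of a muscle gene needed for myoblast fusion, stood at 12493 ± 3129 CPM against 51.9 ± 75.3 and 251 ± 221 CPM, with a log2 fold change of 6.93 (SE 0.71, edgeR adjusted p = 1.60e-06). Ddc_-0.47, of the dopa decarboxylase gene active in cuticle and neurons, rose from 9.04 ± 3.49 and 14.0 ± 7.87 CPM to 985 ± 192 CPM. The hairy element h_HHRE, of a pair-rule repressor, had a log2 fold change of 7.39 (SE 0.82), the vasa germline element vas_construct16 7.57 (SE 0.95), and Sox15_regionB 8.09 (SE 1.10). The esterase element Est-6_D-511 had 6.64 (SE 0.79) and CG4364_upstreamCRM 7.03 (SE 0.81). DHS+K27me3_CtBPoverlap_2267 stood at 9.21 (SE 1.21), and among elements named after binding regions of the corepressors CtBP and Groucho E_0_12h_dCtBP7667.region_4530 had 8.72 (SE 0.96) and E0_12_GROAviva_ChIP_chip.region_481 7.60 (SE 0.99). Neither class was called higher more often than the other elements (11.1% of CtBP regions against 16.9%, 15.6% of Groucho regions against 16.0%). Regulators of early patterning followed: the terminal gap gene element tll_D3 had a log2 fold change of 6.08 (SE 1.53), the Notch target element E(spl)_m8-0.46 5.82 (SE 1.16) and the proneural element ac_0.8 5.59 (SE 1.34). The largest fitted value, 10.31 (SE 2.53) for E0_12_GROAviva_ChIP_chip.region_287, described its data poorly, as the log2 ratio of its mean CPM, 2759 in low-GFP against 517 in CD2+ and 314 in CD2- cells, was 2.73, and its edgeR adjusted p rose from 0.00454 to 0.316 without the experiment term. One further element was chosen after its values were seen. nvy_CRM100, of the nervy corepressor gene, made up 14.8 ± 7.02% of round 1 low-GFP counts against 0.899 ± 0.356% in CD2+ and 0.534 ± 0.374% in CD2- cells (mean ± SD, n = 6), with a log2 fold change of 5.45 (SE 0.59, edgeR adjusted p = 2.36e-06).

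Elements that were depleted from low-GFP cells in round 1 were mostly abundant in the controls. Falls are harder to detect than rises: in simulated data this fit recovered 71.0% of elements raised 16-fold and 39.2% of those lowered 16-fold. The abundance of the depleted elements is therefore not separated from what could be detected. BiTS-ChIP_K4me1+K27me3+K27ac_96 fell from 13527 ± 6948 CPM in CD2+ and 8865 ± 1677 CPM in CD2- cells to 1784 ± 783 CPM, a log2 fold change of -2.63 (SE 0.37, edgeR adjusted p = 2.55e-05). Among elements below 0 on every day, the lowest fold changes were those of E0_12_GROAviva_ChIP_chip.region_43 at -3.84 (SE 0.80), bib_5924, of the big brain gene of neural fate choice, at -3.18 (SE 0.68), and E_0_12h_dCtBP7667.region_3484 at -3.01 (SE 0.86). Next in that set were DHS+K27me3_intergenic_2153 at -2.82 (SE 0.55), the spineless element ss_P732 at -2.68 (SE 0.67), ChIPCRM2497 at -2.60 (SE 0.55) and the head gap gene element ems_ems_ARFE-subA at -2.41 (SE 0.48). E_0_12h_dCtBP7667.region_2748 and the Wnt antagonist element nkd_8756 both stood at -2.56 (SE 0.89 and 0.88). nkd_IntE_255, below 0 on 5 of 6 days, was called at -2.91. All these falls are measured against 0. The 8 E. coli control elements tested in the same fit had a median of -2.04, with 1 called higher and 0 lower. Whether the depleted elements fell further than these controls was not tested.

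Across round 1, 358 elements were tested with edgeR and 93 were called, 57 higher and 36 lower in low-GFP cells. The balance depended on the scaling: the split was 47 higher and 56 lower with total counts, and 58 and 27 with libraries scaled to the E. coli control elements. Falls were harder to detect than rises in this comparison, as given above, and whether this shaped the balance was not tested. Against CD2+ cells alone, simulated 16-fold rises and falls were recovered alike (48.0% and 50.5%), those of 64-fold less so (75.0% and 64.6%). The split there was 44 higher and 30 lower. The calls of E_0_12h_dCtBP7667.region_2748 and nkd_8756 lay near the threshold, and without single days their log2 fold changes ran from -2.90 to -2.26 and from -2.84 to -2.10. The first was lost without day 1, 2, 3 or 5 or the low-GFP library of day 4 (edgeR adjusted p up to 0.141), the other without any of days 1 to 4 or that same library (up to 0.121), with read 2 counts (0.0519) and with E. coli scaling. E_0_12h_dCtBP7667.region_3484 was lost without day 3 (edgeR adjusted p = 0.0612).

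**Figure D1:**
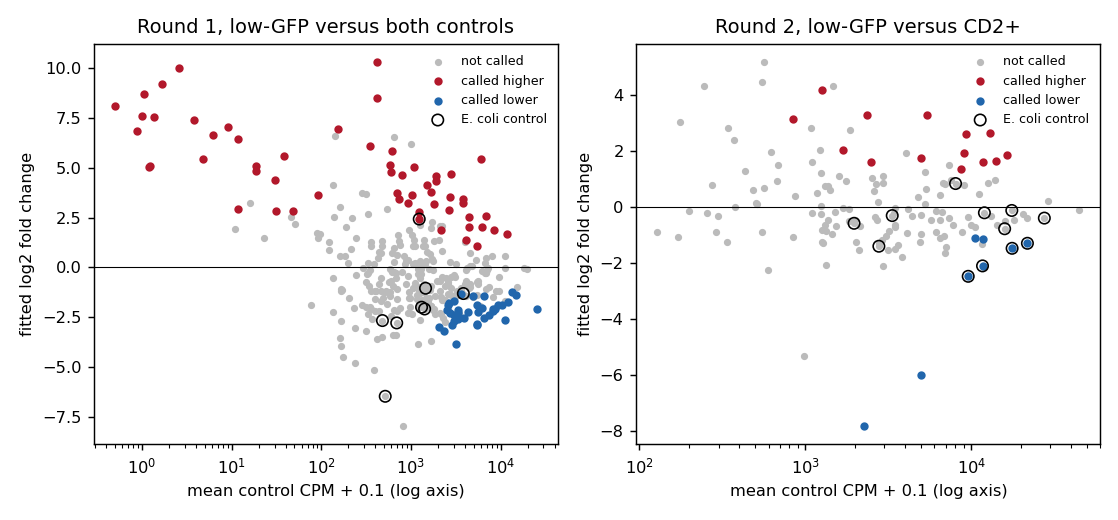
Fitted log2 fold change of each tested element (y axis) against its mean abundance in the control sorts in CPM plus 0.1 (log x axis), for round 1 low-GFP against both controls and round 2 low-GFP against CD2+ cells; red points were called higher, blue lower, grey not called, and open circles are E. coli controls. Many of the largest rises in round 1 lie at the rare end of the axis, while elements called lower lie in its abundant part. An element rare in the controls often enters the test only where its low-GFP counts are high, so the filter itself favours rises at the rare end.

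Among lists of genes fixed before the data were examined, no list differed from the other elements in round 1 (camera adjusted p from 0.155 to 0.799). Of 21 tested elements of segmentation genes, 5 were higher, 5 lower and 11 did not pass, with 6 higher and 5 lower when adjusted over the list alone. Their median log2 fold change was -0.10, or 0.37 with collection day as a block and -0.80 with total counts. Their mean was 0.38, and the test leaned up (camera adjusted p = 0.799, adjusted p = 0.795 with an estimated correlation). The fushi tarazu element ftz_5'delta276 rose from 661 and 545 CPM to 15885 CPM, a log2 fold change of 4.77 (SE 0.49), and the hedgehog element hh_4075 had 3.22 (SE 0.80), a call that was lost without day 1 (edgeR adjusted p = 0.0637). prd_deltaQ, of the pair-rule gene paired, did not pass at 3.74 (edgeR adjusted p = 0.0588), but passed with collection day as a block (0.0145). Of 17 elements of tracheal and ectodermal organ genes, 2 were higher, 5 lower and 10 did not pass, the same when adjusted over the list alone, with a median of -1.39 (camera adjusted p = 0.155, adjusted p = 0.329 with an estimated correlation). The eyeless element ey_UE0.9 (log2 fold change 3.19, SE 0.60) and the cut element ct_ct-3 (5.04, SE 1.09) were the higher ones, and vg_quadrant_enhancer (-2.39, SE 0.55) and ey_5D11 (-2.14, SE 0.63) had the lowest values. Of 20 elements of gap and head genes, 4 were higher, 1 lower and 15 did not pass, unchanged when adjusted over the list alone, with a median of -0.15, a mean of 0.53 and an upward test (camera adjusted p = 0.799, adjusted p = 0.795 with an estimated correlation). Besides tll_D3 these were the orthodenticle element oc_otd-186 (1.87, SE 0.38), hkb_0.6kbRIRV (2.60, SE 0.69) and the maternal hunchback element hb_matDm0.5-lacZ (8.51, SE 2.49). The huckebein call was lost without day 4 (edgeR adjusted p = 0.0556) and with total counts (0.0610). The hunchback call was lost without day 2 or day 3 (up to 0.0924), with collection day as a block (0.05001) and without the experiment term (0.390).

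The lists of the tissues flanking the mesoderm had few called members in round 1. Of 9 neuroectoderm and midline elements, 1 was higher, ac_0.8, none lower and 8 did not pass, with 1 higher when adjusted over the list alone and a median of 2.10 (camera adjusted p = 0.155, adjusted p = 0.375 with an estimated correlation). vnd_NEE, of the ventral nervous system gene vnd, stood at 4.12 (SE 1.83, edgeR adjusted p = 0.112) and the thisbe FGF element ths_Neu4_early_embryonic_enhancer at 3.68 (SE 1.52, edgeR adjusted p = 0.0871). None of 8 dorsal ectoderm elements passed, also when adjusted over the list alone (0), with a median of 1.31 (camera adjusted p = 0.369, adjusted p = 0.381 with an estimated correlation). Doc3_7731 had the largest value there, 2.52 (edgeR adjusted p = 0.167). Among 10 elements of mesoderm genes 0 passed, and 0 when adjusted over the list alone, with a median of -0.13 and a mean of -0.22 (camera adjusted p = 0.799, adjusted p = 0.795 with an estimated correlation). The heart gene element tin_tin103C, at 1.63 (edgeR adjusted p = 0.353), passed with collection day as a block (0.0302). Only 1 Hox and 2 Notch elements were tested, too few for a list test, and lab_1.0 stood at -1.22 and HLHm5_m5-0.13 at 1.98, neither past the threshold (edgeR adjusted p = 0.543 and 0.0524). By fry, which asks only whether a list moves on balance one way, 5 of the lists passed, dorsal ectoderm and neuroectoderm upward (adjusted p = 0.00141 each), segmentation upward (0.0141), gap and head upward (0.0460) and tracheal downward (0.00252), and the mesoderm list did not (0.766, upward, against the sign of its mean). Fry tests against a fold change of 0, and the fold changes of whole lists move with the scaling.

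Against CD2+ cells alone, the sort that low-GFP cells were part of, 74 of 358 elements were called by edgeR, 44 higher and 30 lower, and the split was 39 and 48 with total counts and 41 and 18 with E. coli scaling. Z600_z600-lacZ had a log2 fold change of 9.70 (SE 1.39, edgeR adjusted p = 0.000132), CAD2_sns 8.18 (SE 1.02, edgeR adjusted p = 7.86e-05) and BiTS-ChIP_K4me1+K27me3+K27ac_96 -2.94 (SE 0.40, edgeR adjusted p = 0.000132). No list passed camera here (adjusted p from 0.117 to 0.969), and the estimated correlation gave adjusted p = 0.485 for neuroectoderm and 0.250 for tracheal elements. By fry, dorsal ectoderm and neuroectoderm passed upward (adjusted p = 0.0200 and 0.0104) and tracheal elements downward (0.00225). Segmentation (fry adjusted p = 0.115), gap and head (0.653) and mesoderm elements (0.653) did not pass it. tll_D3 did not pass at 5.32 (edgeR adjusted p = 0.0708), but did with collection day as a block (0.00751), as did prd_deltaQ (0.0459). Of the 30 named elements called here, 11 lost the call without a single day, among them E0_12_GROAviva_ChIP_chip.region_287 (10.01; lost without day 4, 5 or 6, edgeR adjusted p up to 0.118), ac_0.8 (5.70; without any of days 2 to 5, up to 0.108) and E(spl)_m8-0.46 (5.60; without day 5, 0.0503). The same held for ey_5D11 (-2.70; lost without day 3, edgeR adjusted p = 0.117), E_0_12h_dCtBP7667.region_3484 (-3.15; without day 3 or 5, up to 0.156) and E_0_12h_dCtBP7667.region_3509 (-2.67; without day 3 or 5, up to 0.115). The remaining 5 were ct_ct-3 (4.98; without day 2 or 5, edgeR adjusted p up to 0.0542), ey_UE0.9 (2.95; without day 4, 0.0548), hb_matDm0.5-lacZ (8.99; without any of days 1 to 4, up to 0.145), nkd_IntE_255 (-3.17; without any day but day 3, up to 0.198) and ovo_del-ap-del-5 (6.70; without any day but day 2, up to 0.134). Of these, E0_12_GROAviva_ChIP_chip.region_287 (0.508), ac_0.8, hb_matDm0.5-lacZ (0.456), nkd_IntE_255 (0.0903) and ovo_del-ap-del-5 (0.108) also lost the call without the experiment term (edgeR adjusted p), and E_0_12h_dCtBP7667.region_3484 (0.0696), nkd_IntE_255 (0.0530) and ovo_del-ap-del-5 (0.0644) with E. coli scaling. ovo_del-ap-del-5 lost it with read 2 (0.0530), summed reads (0.0522) and no filter (0.0501) as well. With collection day as a block, hb_matDm0.5-lacZ (edgeR adjusted p = 0.108), nkd_IntE_255 (0.2) and ovo_del-ap-del-5 (0.221) lost the call too.

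The CD2+ and CD2- control sorts were compared to see whether elements differ in recovery between mesodermal and other cells before any selection on GFP. Of 358 elements 0 were called by edgeR, 6 had an unadjusted p under 0.05, and DESeq2 called 3. On simulated data the same test recovered 8.04% of elements changed 4-fold, 46.7% of those changed 16-fold and 66.0% of those changed 64-fold.

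The experiments of round 1 were also fitted apart. In simulated data the fits of experiments 1 and 2 recovered 45.0% and 35.0% of elements raised 16-fold, but 16.2% and 11.0% of those lowered 16-fold. Experiment 1 gave 48 calls in 354 elements, 34 higher and 14 lower, and experiment 2 gave 43 in 344, 35 higher and 8 lower (edgeR). The splits were 30 and 21, and 23 and 17, with total counts, and 39 and 3, and 17 and 3, with E. coli scaling. With 3 days each, single libraries moved these counts. In experiment 1 the count fell to 12 without CD2- of day 3, 14 without CD2+ of day 2, 15 without CD2+ of day 1, 17 without CD2- of day 2, 20 without low-GFP of day 3, 21 without low-GFP of day 1, 22 without low-GFP of day 2 and 25 without CD2+ of day 3. In experiment 2 it fell to 5 without CD2- of day 5, 7 without CD2- of day 4, 10 without CD2+ of day 4 and 19 without low-GFP of day 5. Over the 319 elements tested in both, log2 fold changes correlated with Pearson's r of 0.719 and Spearman's rho of 0.663 across elements, which are not independent replicates, and 80.6% had the same sign. There were 24 elements called higher in both experiments, against 2.98 expected (Fisher's exact p = 2.87e-24), and 2 called lower in both, against 0.351 (Fisher's exact p = 0.0431). No element was called in opposite directions. The test for a fold change that differed between the experiments called 0 elements with edgeR, 12 had an unadjusted p under 0.05, and DESeq2 called 11.

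**Figure D2:**
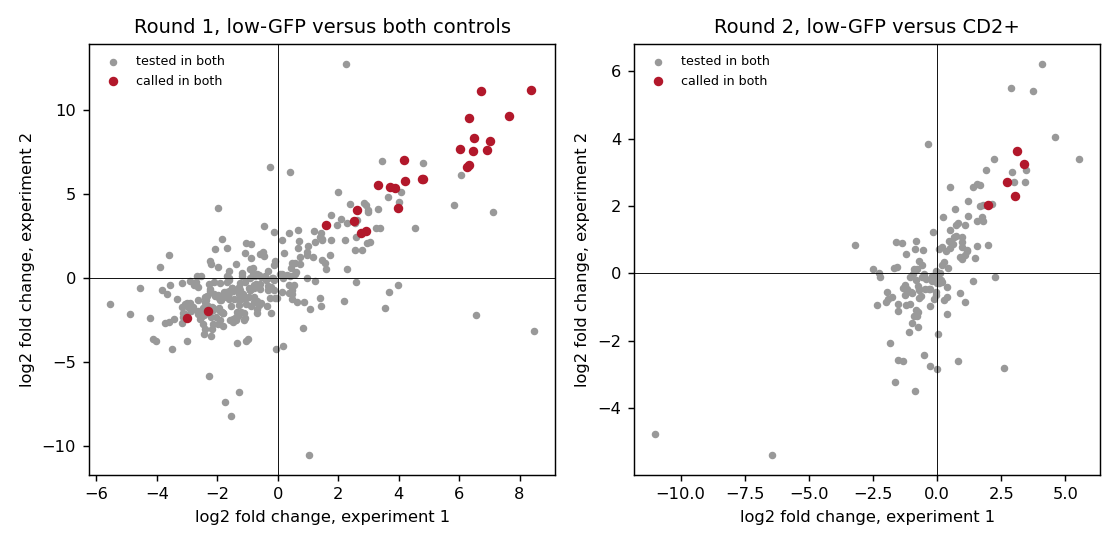
Log2 fold change of each element in experiment 1 (x axis) against experiment 2 (y axis), for round 1 against both controls and round 2 against CD2+ cells, with elements called in both experiments in red. Most points lie in the quadrants of equal sign, 80.6% in round 1 and 77.4% in round 2.

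Round 2 asked the same of a smaller pool with 173 elements listed in round 1 as well. The pannier GATA factor elements pnr_P3 and pnr_P4, of a gene of dorsal ectoderm and heart, rose from 5381 ± 2330 to 52001 ± 13370 CPM and from 2344 ± 1273 to 23384 ± 13128 CPM (mean ± SD, n = 6). Their log2 fold changes were 3.29 (SE 0.30, edgeR adjusted p = 1.52e-05) and 3.27 (SE 0.38, edgeR adjusted p = 5.61e-05). The head gap gene element oc_otd-186 made up 6.79 ± 1.99% of low-GFP counts against 1.55 ± 0.548% of CD2+ counts, with a log2 fold change of 2.63 (SE 0.30, edgeR adjusted p = 5.61e-05). ths_Neu4_early_embryonic_enhancer, of an FGF ligand made in the neuroectoderm, had 2.60 (SE 0.35, edgeR adjusted p = 0.000227), and sog_shadow, of the BMP antagonist short gastrulation, 1.92 (SE 0.27, edgeR adjusted p = 0.000342). The segment polarity element gsb_fragIV followed at 1.84 (SE 0.33, edgeR adjusted p = 0.00193) and CRM_1807 at 1.65 (SE 0.28, edgeR adjusted p = 0.00150). Among elements that fell, Ubx_BXD-C, from the bithoraxoid region of the Hox gene Ubx, dropped from 4949 ± 3851 to 93.6 ± 113 CPM, a log2 fold change of -5.98 (SE 1.31, edgeR adjusted p = 0.0109), while CRM_Ubx_BXD-A stood at -0.04. These 8 elements were called in every fit without a single day and in every alternative setting in which they were tested.

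**Figure D3:**
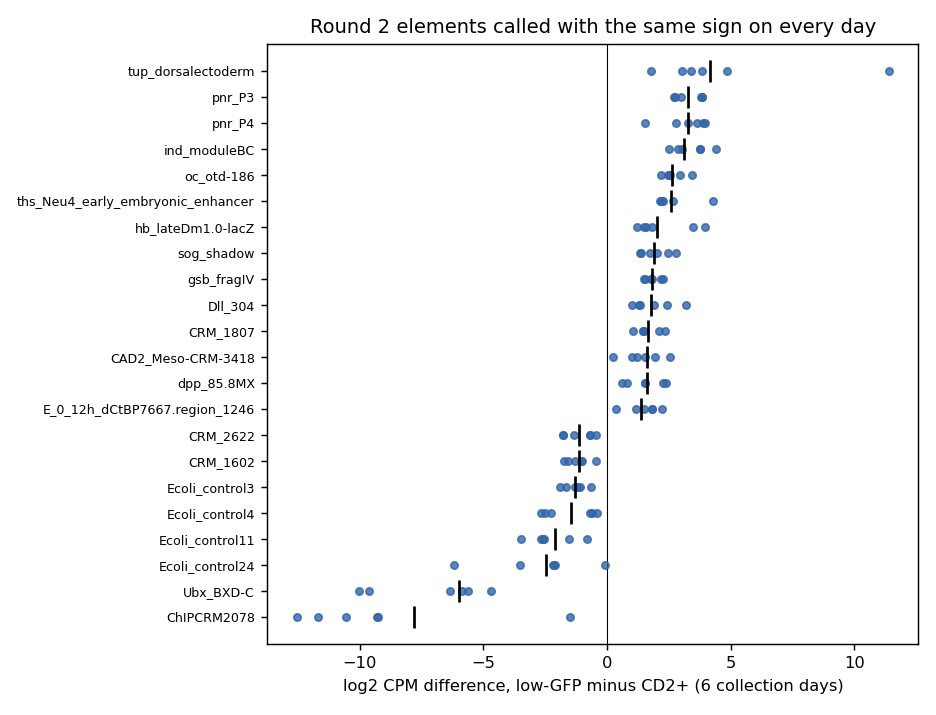
The 22 round 2 elements called with the same sign on every day, each with 6 dots, the log2 CPM difference between low-GFP and CD2+ cells on each collection day (x axis), and a vertical tick at the fitted log2 fold change. The dots of pnr_P3 stay close to 3.29, while those of ChIPCRM2078 and tup_dorsalectoderm spread widely.

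In all, 22 of 155 elements were called in round 2 by edgeR, 14 higher and 8 lower. With collection day as a block, 31 were called, 20 higher and 11 lower, including all 22. The split was 8 higher and 17 lower with total counts and 23 and 2 with E. coli scaling. Without 1 day the count was 12 (day 1), 9 (day 2), 14 (day 3), 28 (day 4), 11 (day 5) or 14 (day 6), and 13 of the calls were lost without at least 1 of them. The dorsal ectoderm element tup_dorsalectoderm (log2 fold change 4.17, SE 1.25) was lost without any day but day 4 (edgeR adjusted p up to 0.158). The neuroectoderm element ind_moduleBC (3.13, SE 0.82) was lost without day 1, 2, 3 or 5 (edgeR adjusted p up to 0.0994), and hb_lateDm1.0-lacZ (2.03, SE 0.52) without day 1, 2, 3 or 6 (up to 0.0847). Dll_304, of the limb gene Distal-less (1.76, SE 0.48), needed days 2, 3 and 6 (edgeR adjusted p up to 0.123), E_0_12h_dCtBP7667.region_1246 (1.38, SE 0.32) days 2, 5 and 6 (up to 0.0847), dpp_85.8MX (1.60, SE 0.48) all days but day 3 (up to 0.127) and CAD2_Meso-CRM-3418 (1.62, SE 0.48) all but day 4 (up to 0.176). Among lower elements, ChIPCRM2078 (-7.81, SE 2.15) was lost without day 1, 2, 3 or 5 (edgeR adjusted p up to 0.120), CRM_1602 (-1.15, SE 0.32) without any single day (up to 0.107) and CRM_2622 (-1.12, SE 0.30) without any day but day 4 (up to 0.127). Total counts also ended the calls of tup_dorsalectoderm (edgeR adjusted p = 0.0636), hb_lateDm1.0-lacZ (0.0717), Dll_304 (0.0717), E_0_12h_dCtBP7667.region_1246 (0.1), dpp_85.8MX (0.1) and CAD2_Meso-CRM-3418 (0.148). Read 2 counts ended those of tup_dorsalectoderm (edgeR adjusted p = 0.0593), dpp_85.8MX (0.0679), CAD2_Meso-CRM-3418 (0.0594) and ChIPCRM2078 (0.0635). CRM_1602 and CRM_2622 were lost with E. coli scaling (edgeR adjusted p = 0.336 each), tup_dorsalectoderm without the experiment term (0.0793) and dpp_85.8MX with the size factors of the authors (0.0589).

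The lists of tissues flanking the mesoderm and the mesoderm list passed camera in round 2 with its preset correlation, and only the neuroectoderm list also with an estimated one. Of 8 dorsal ectoderm elements, 4 were higher (pnr_P3, pnr_P4, tup_dorsalectoderm and dpp_85.8MX), none lower and 4 did not pass, with 5 higher when adjusted over the list alone. Their median log2 fold change was 1.79 (camera adjusted p = 0.00376, but adjusted p = 0.0598 with an estimated correlation, which does not pass), and called rises made up 50% of the list against 6.80% of the other elements (Fisher's exact test, adjusted p = 0.0170). Of 11 neuroectoderm and midline elements, 3 were higher (ind_moduleBC, ths_Neu4_early_embryonic_enhancer and sog_shadow), none lower and 8 did not pass, the same when adjusted over the list alone. Their median was 2.60 (camera adjusted p = 0.00376, adjusted p = 0.0481 with an estimated correlation), while called rises, 27.3% of the list against 7.64% of the others, were not more frequent past the threshold (Fisher's exact test, adjusted p = 0.215). ind_moduleA (4.45), brk_NEE-long (4.32) and vnd_NEE (4.32) had the largest values of that list without passing (edgeR adjusted p = 0.145, 0.153 and 0.233), and ind_moduleA passed with collection day as a block (0.0152). Of 6 elements of mesoderm genes, 2 were higher, pnr_P3 and pnr_P4, which are also on the dorsal ectoderm list, and 4 did not pass, with 2 higher when adjusted over the list alone. The median was 0.42, or -0.06 with total counts (camera adjusted p = 0.0211, adjusted p = 0.0598 with an estimated correlation), and CAD2_htl, of a mesodermal FGF receptor, stood at -0.45.

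By camera, the remaining lists did not differ from other elements in round 2. By fry, dorsal ectoderm (adjusted p = 0.000423), neuroectoderm and mesoderm (0.000185 each), gap and head (0.0107) and tracheal elements (0.0208) passed upward. Hox elements passed fry downward (adjusted p = 0.00263), and segmentation elements did not pass it (0.255). Of 12 gap and head elements, 2 were higher, oc_otd-186 and hb_lateDm1.0-lacZ, and 10 did not pass, the same when adjusted over the list alone, with a median of 0.16, or -0.35 with total counts (camera adjusted p = 0.166, adjusted p = 0.196 with an estimated correlation). Of 3 Hox elements, 1 was lower, Ubx_BXD-C, and 2 did not pass, the same when adjusted over the list alone, with a median of -0.45, or -0.91 with collection day as a block and -0.82 with total counts (camera adjusted p = 0.166, adjusted p = 0.196 with an estimated correlation). Of 6 segmentation elements, 1 was higher, gsb_fragIV, and 5 did not pass, the same when adjusted over the list alone, with a median of 0.40, or -0.12 with total counts (camera adjusted p = 0.557, adjusted p = 0.589 with an estimated correlation). Of 3 tracheal and ectodermal organ elements, 1 was higher, Dll_304, and 2 did not pass, the same when adjusted over the list alone, with a median of -0.07, a mean of 0.21 and an upward test (camera adjusted p = 0.557, adjusted p = 0.589 with an estimated correlation). No element of the Notch list was tested in round 2.

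The E. coli elements served as sequences without regulatory history in flies. In round 2, 4 of 12 were lower in low-GFP cells, Ecoli_control24 (log2 fold change -2.47, SE 0.71), Ecoli_control11 (-2.10, SE 0.58), Ecoli_control4 (-1.47, SE 0.37) and Ecoli_control3 (-1.29, SE 0.29), with a median of -0.68 over the 12. Only the call of Ecoli_control3 held without every single day. Ecoli_control24 was lost without any day but day 3 (edgeR adjusted p up to 0.107), Ecoli_control11 without day 1, 2, 5 or 6 (up to 0.110) and Ecoli_control4 without day 2 or 5 (up to 0.0951). Ecoli_control24 (edgeR adjusted p = 0.145) and Ecoli_control11 (0.122) also lost the call without the experiment term. With libraries scaled to the summed counts of these elements, their median was -0.03, and 0 were lower and 1 higher. That scaling holds their sum equal across libraries by construction, but does not centre the single elements. In round 1 the 8 tested had a median of -2.04, and still -1.76 with that scaling. Called rises made up 12.5% of these controls against 16.0% of the other elements, so the controls were not called higher clearly less often. Ecoli_control22 alone was called, as higher, at 2.43 (SE 0.58, edgeR adjusted p = 0.00394). It had 6783 ± 4989 CPM in low-GFP against 1588 ± 860 CPM in CD2+ and 881 ± 639 CPM in CD2- cells, and was named after its values were seen.

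Within round 2, experiment 1 gave 8 calls in 159 elements, 7 higher and 1 lower, and with collection day as a block it gave 13, 11 higher and 2 lower. The count of 8 fell to 5 without low-GFP of day 1, 5 without low-GFP of day 2 and 4 without CD2+ of day 3 (edgeR). Experiment 2 gave 8 calls in 154 elements, 8 higher and 0 lower, which fell to 4 without CD2+ of day 4, 2 without CD2+ or low-GFP of day 5, and 3 without CD2+ or low-GFP of day 6. The splits were 4 higher and 2 lower, and 2 and 2, with total counts, and 19 and 1, and 11 and 0, with E. coli scaling. The elements pnr_P3, pnr_P4, oc_otd-186, ths_Neu4_early_embryonic_enhancer and sog_shadow were called higher in both, 5 against 0.384 expected (Fisher's exact p = 2.20e-06). Across the 146 elements tested in both, r was 0.722 and rho 0.664, and 77.4% had the same sign. The test for a difference between the experiments called 0 elements with edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 0.

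Of the 173 shared elements, 27 were tested in round 1, 141 in round 2 and 25 in both, and 117 had no read 1 count in any round 1 library. Across these 25, log2 fold changes of round 1 against both controls and of round 2 had r of 0.699 and rho of 0.718, and 88.0% had the same sign. With CD2+ cells as the control in both rounds, r was 0.798 and rho 0.801, and 92.0% had the same sign. oc_otd-186 (1.87 in round 1, 2.63 in round 2) and gsb_fragIV (1.66, SE 0.48, and 1.84) were called higher in both, which 1.40 elements would be by the margins alone (Fisher's exact p = 0.597). With CD2+ cells as the control in both rounds, only oc_otd-186 was (Fisher's exact p = 0.367). Of 57 elements called higher in round 1, 7 were tested in round 2 and 6 of those were above 0 there, with a median of 1.49.

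Low-GFP libraries were dominated by fewer elements than control libraries. The 10 highest elements held 42.2 ± 9.63% of counts in round 1 low-GFP libraries, 21.8 ± 1.59% in CD2+ and 21.3 ± 3.33% in CD2- libraries (mean ± SD, n = 6). In round 2 they held 40.3 ± 3.75% against 30.3 ± 2.10% in CD2+ libraries. The difference from CD2+ was 20.4 points in round 1 (18.9 in experiment 1 and 21.9 in experiment 2) and 10.0 points in round 2 (9.23 and 10.8), with the low-GFP library higher on 6 of 6 days. Each comparison reached 0.0313, the smallest two-sided p that an exact sign-flip test over 6 days allows, and 0.0833 after adjustment over 8 tests, which does not pass. The number of elements detected was 360.2 ± 9.15 in low-GFP and 346.5 ± 16.8 in CD2+ libraries of round 1 (exact sign-flip p = 0.188, adjusted 0.375) and did not differ in round 2 (exact sign-flip p = 0.906).

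**Figure D4:**
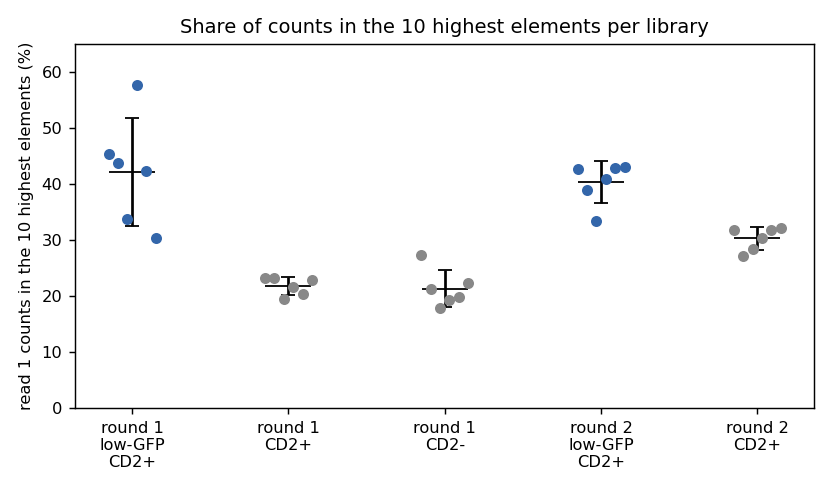
Percent of read 1 counts held by the 10 highest elements of each library (y axis) by sorted population and round; each dot is 1 library (n = 6 per group), and marks with bars are mean ± SD. Low-GFP libraries average 42.2% in round 1 and 40.3% in round 2, above every control group's mean of 21.3% to 30.3%.

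The deposited tables of the authors list adjusted p-values for each experiment. In round 1 they held 81 of 349 elements under 0.05 for experiment 1 (62 higher, 19 lower) and 66 of 352 for experiment 2 (63 higher, 3 lower), and 49 were higher in both against 10.2 expected. In round 2 the counts were 19 of 153 (17 higher, 2 lower) and 25 of 149 (24 higher, 1 lower), with 15 higher in both against 2.89 expected. Of the elements called here and listed there, 37 of 46, 33 of 42, 8 of 8 and 8 of 8 were also called in the authors' tables, in the order round 1 experiment 1 and 2, round 2 experiment 1 and 2. Of the elements called there and tested here, 37 of 78, 33 of 54, 8 of 19 and 8 of 25 were called here, in the same order. Log2 fold changes correlated across elements at r of 0.969, 0.987, 0.999 and 0.999, from the same libraries on both sides.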

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

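Of the tests in this part, those on rare elements against counting noise and against a single experiment, on library scaling and on presence in round 1 were chosen after the results were seen, while those on the round 1 pool, on matched abundance, on the comparison of rounds and on redistributed labels were fixed before.

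Single days stood far from the other 5 in 5 of 67 groups of 6 values, where about 1 in 20 groups would by chance. The groups were measures per library (read totals, elements detected, shares of the highest elements) and daily log2 CPM differences of named elements. All 5 were among the daily differences, so the rate there was higher than 5 of 67. E0_12_GROAviva_ChIP_chip.region_43 had -11.15 on day 1 of round 1, against -5.43 for the next day and -2.29 at the other end, and without that day its log2 fold change was -3.45 (edgeR adjusted p = 0.000703). ss_P732 had -7.92 on day 4 of round 1, against -3.20 and -1.77, and -2.39 without that day (edgeR adjusted p = 0.00748). tup_dorsalectoderm had 11.40 on day 5 of round 2, against 4.86 and 1.78, and without that day its value was 3.63 and the call was lost (edgeR adjusted p = 0.0797). ths_Neu4_early_embryonic_enhancer had 4.28 on day 1 of round 2, against 2.67 and 2.14, and 2.27 without that day (edgeR adjusted p = 0.000789). ChIPCRM2078 had -1.51 on day 6 of round 2, against -9.26 to -12.5 on the other days, and -11.28 without day 6 (edgeR adjusted p = 9.51e-05).

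In round 1, 15 of the 57 elements called higher, Z600_z600-lacZ and h_HHRE among them, were rare in both control sorts, with a mean under 20 CPM. Rare elements were therefore chosen in 1 experiment alone and followed in the other: of 18 called higher in experiment 1, 12 were tested in experiment 2 and 11 called higher there (61.1% with untested elements counted as not called, against 6.85% of the other elements, Fisher's exact p = 2.49e-08), and of 13 called in experiment 2, 12 were tested in experiment 1 and 11 called higher there (84.6% against 5.14%, Fisher's exact p = 8.94e-12), which argues against sampling noise that differs between experiments. Whether a single experiment carries the enrichment stays open for the 15 as a set: 73.3% of the 15 were called higher in each experiment fitted alone, short of the bar of 80%. The 11 called higher in each were picked by those same calls, so the calls are no separate evidence on this question. Of the other 4, E_0_12h_dCtBP7667.region_2659, ct_ct-3 and Rh3_promoter were not tested in experiment 2 and Sgs4_OPSL passed in neither. The 12 tested in both are not judged apart, since an element this rare in the controls often enters a test only where its low-GFP counts are high. Whether the enrichment is specific to the flies or PCR products of round 1 could not be told, as 0 of the 15 were tested in round 2, and no biological explanation was tested.

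E. coli control elements were lower in low-GFP cells of round 2, with 4 of 12 called, and as a class passed camera with a preset correlation (adjusted p = 0.0327) but not with an estimated one (adjusted p = 0.299). Scaling moves all elements of a library alike, and the gap to the median of all elements was -0.44 to -0.47 under every scaling. With 1 exception, 4 to 6 were called lower. The exception was scaling to the summed counts of these elements (0 called lower), which holds their sum equal across libraries by construction. Scaling therefore does not make the gap, but whether the gap exceeds chance is open, since the difference from the other elements, -0.54, was at the 5.51 percentile of random sets. Sets matched on abundance in the CD2+ sort argue against abundance (2.4 percentile of 10000), though they treat elements as independent. Round 1 leaves open whether the same holds there, since the median of its 8 elements was at the 1.06 percentile of matched sets but the class did not pass camera (adjusted p = 0.555) and the 1 call, Ecoli_control22, was higher.

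A difference between rounds for the same elements was anticipated before the data were examined, and the data do not decide it. For 20 elements fold changes correlated at 0.742 between rounds, 0.716 within round 1 and 0.876 within round 2. Within round 1 the correlation exceeded that between rounds by -0.0258 (95% bootstrap interval -0.211 to 0.259). Within round 2 it did so by 0.134 (-0.00772 to 0.338). The value between rounds used fits of 6 days, those within a round fits of 3 days, which rest on fewer libraries. Round 1 was fitted against both controls and round 2 against CD2+ cells, so these differences do not compare like with like. With the 12 abundant elements alone the correlation between rounds was 0.768, against 0.699 over all 25 elements tested in both rounds. The change was 0.0682 (95% bootstrap interval -0.254 to 0.249). An interval that holds 0 had been taken in advance as evidence against a pool effect, and a rise of the correlation by 0.2 or less as evidence against noise of rare elements, but with 20 and 12 elements the intervals are too wide to decide either.

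Group labels were redistributed over the libraries to see how often as many calls arise. For round 1 against both controls the true labels alone reached 93 calls (1 of 100 splits, the highest other split 33), against CD2+ 74 (1 of 100, highest other 0), and in round 2 22 (1 of 100, highest other 8). Experiment 1 of round 1 reached 48 in 1 of 100 splits (highest other 0), and experiment 2 reached 43 in 2 of 100, the other one with 52 calls exchanging only CD2+ and CD2- libraries while keeping the low-GFP set. For the experiments of round 2 (8 calls each, 1 of 10 splits each, highest other 2) there were too few splits to tell. CD2+ against CD2- (100 of 100 splits, highest other 2) and the interactions (10 of 10, highest other 0) had 0 calls, which every split reaches, so these counts say nothing. Exchanging labels only within a collection day gave 1 of 100 splits for round 1 against both controls (highest other 39), 1 of 32 against CD2+ (highest other 0) and 1 of 32 in round 2 (highest other 0). For experiments 1 and 2 of round 1 it gave 4 of 100 each, of which 3 others kept the low-GFP set.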

How the results depend on the processing

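No call of a named element changed direction under any alternative, and no list test past its threshold did with total counts or with collection day as a block, the only 2 run on lists, but the balance of calls and some medians did: with total counts it turned from 57 higher and 36 lower to 47 and 56 in round 1, from 44 and 30 to 39 and 48 against CD2+, and from 14 and 8 to 8 and 17 in round 2. The medians of the mesoderm (0.42 to -0.06), gap and head (0.16 to -0.35), segmentation (0.40 to -0.12) and gene-named elements (0.38 to -0.09) of round 2 then fell below 0, as the median of all elements moved from -0.20 to -0.72. In round 1 medians fell for dorsal ectoderm (1.31 to 0.56), neuroectoderm (2.10 to 1.42), mesoderm (-0.13 to -0.89), gap and head (-0.15 to -0.80), segmentation (-0.10 to -0.80) and tracheal elements (-1.39 to -2.03). The median of all elements there moved from -0.61 to -1.23. Those 66 list results kept their side of the threshold, the pooled counts of low-GFP calls stayed within 1.5 times except for round 2 without single days, the adjusted p of the library shares of the 10 highest elements was 0.0833 in every setting, which the smallest p that 6 days allow fixes, so it shows nothing about stability, and unless stated otherwise the cause of a change was not tested. DESeq2 called more elements: 83 in experiment 1 and 83 in experiment 2 of round 1 (48 and 43 with edgeR), 26 and 17 in the experiments of round 2 (8 and 8), 3 between CD2+ and CD2- (0) and 11 in the round 1 interaction (0). In simulated data 4.08% to 37.0% of its calls were false, from 3 sets per comparison drawn with the dispersions of edgeR. At least 100 counts in every library of 1 population gave 13 calls in experiment 1 of round 2, and moved the correlation of the experiments of round 1 from 0.719 to 0.857. Collection day as a replicate block gave 13 calls in experiment 1 of round 2, 88 in round 1 against both controls (84 of the 93 kept), 73 against CD2+ (66 of 74) and 31 in round 2 (all 22 kept). Scaling to the E. coli elements, chosen after seeing the data, gave 20 calls in experiment 2 of round 1 and 20 in experiment 1 of round 2. Experiment 2 of round 2 had 4 calls with total counts, 2 without a filter and 5 with the size factors of the authors, also chosen after seeing the data. Leaving out 1 day or library gave 74 to 93 calls for round 1 against both controls, 50 to 71 against CD2+, 0 to 0 for CD2+ against CD2-, 12 to 39 and 5 to 52 for the experiments of round 1, 9 to 28 for round 2, and 4 to 10 and 2 to 8 for its experiments, with fewer libraries in each fit. Without the low-GFP library of day 4 of round 1, where nvy_CRM100 held 24.0% of counts, and chosen after seeing the data, 78 elements were called, 50 higher and 28 lower. Of the named elements called, 24 of 31 in round 1 against both controls, 19 of 30 against CD2+ and 8 of 22 in round 2 kept their call in every setting that tested them. An element dropped by the filter of a setting was not counted as lost there. Among named elements the block ended the call of hb_matDm0.5-lacZ (adjusted p = 0.05001, against CD2+ 0.108), nkd_IntE_255 (0.2) and ovo_del-ap-del-5 (0.221, both against CD2+), besides the gains named in the report. Read depth sets floors of 0.506 to 1.02 CPM, while the limits set by the numbers of cells and template molecules are not known.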

Other observations

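The elements, name classes and genes in this part were chosen after their values were seen, and the values are given without a test of an explanation.

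Of 4 opsin gene elements tested in round 1, 3 were called higher in low-GFP cells and Rh6_-555_+121 was not (log2 fold change -0.09, edgeR adjusted p = 0.956), and no enrichment of such elements was tested. Rh5_promoter, of a blue opsin, had 232 ± 170 CPM in low-GFP cells against 4.18 ± 3.37 CPM in CD2+ and 5.19 ± 3.32 CPM in CD2- cells (mean ± SD, n = 6), with a log2 fold change of 5.45 (SE 0.86, edgeR adjusted p = 8.74e-05). ninaE_proximal_promoter_region, of the main rhodopsin, had 5.16 (SE 1.35, edgeR adjusted p = 0.00716). Rh3_promoter, of an ultraviolet opsin, had 5.11 (SE 1.25, edgeR adjusted p = 0.00454) but was higher on only 4 of 6 days.

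Several genes had elements on both sides. Of 10 genes with at least 2 called elements in round 1, 5 had elements called in opposite directions. With 57 calls higher and 36 lower in all, unrelated elements would often differ in direction too, so this count shows nothing particular to genes. The tyrosine hydroxylase gene ple had ple_995bp_wound_response_element at 4.16 (SE 0.63, edgeR adjusted p = 6.26e-05) and ple_WE1 at -1.76 (SE 0.35, edgeR adjusted p = 0.000964). The pigment gene ebony had e_coreAbdominalCRE at 1.86 (SE 0.48) and e_A.2 at -2.07 (SE 0.42). The fushi tarazu elements ftz_5'delta276 and ftz_-669_-386 stood at 4.77 and -2.20, hh_4075 and hh_alpha_fragment_(ic-CRE) at 3.22 and -1.46, and ey_UE0.9 and ey_5D11 at 3.19 and -2.14. The other 5 genes moved 1 way, hairy and ovo upward and nkd, ss and trh downward.

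Among name classes, 4 of 14 class I insulator elements were higher and none lower in round 1, ClassI_ins_29 at 3.42 (SE 0.51), ClassI_ins_210 at 3.52 (SE 0.70), ClassI_ins_87 at 3.71 (SE 0.72) and ClassI_ins_196 at 4.33 (SE 1.01), while the class as a whole did not differ from the others (camera adjusted p = 0.555). CtBP regions had 7 higher and 5 lower of 63, and Groucho regions 5 higher and 2 lower of 32. In round 2, 11 of 65 elements named after a gene were higher and 1 lower, with a median log2 fold change of 0.38, or -0.09 with total counts, against -0.42 for the others (camera adjusted p = 0.00638, adjusted p = 0.0415 with an estimated correlation). Called rises made up 16.9% of them against 3.33% of the others (Fisher's exact test, adjusted p = 0.0410).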
